A study of Homo sapiens with 12 samples.

How the data were processed

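Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate histone H3.1/H3.2 (called H3.1 here) and histone H3.3 in MCF10AER/vSrc cells. MCF10A is an established, non-tumorigenic human mammary epithelial line; ER/vSrc denotes an inducible v-Src oncoprotein fused to an estrogen receptor domain. Per the labels, cells were controls or were collected 4 h or 24 h after D-alanine, which per the series design gave reactive oxygen species in the nucleus. The labels give the D-alanine dose as 10 nM. This dose is doubtful, since D-alanine is usually given to cells with D-amino acid oxidase at millimolar concentrations, and it was not checked against another source. The labels gave 12 samples, made of 6 ChIP libraries and 6 input libraries, 1 of each for every histone and time. Reads were single-end and 50 bases long per the labels' protocols.

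Per the submitters' processing notes, the tools were cutadapt 3.7, Bowtie2 2.4.1 and HOMER 4.11.1 with the hg38 build. Per the file headers, enriched regions were called separately in each ChIP library against its input with the histone style of HOMER. The headers gave a peak size of 500 bp, a minimum distance of 1000 bp between peaks and at most 1 tag per bp. They required a fold of 4 over input, a Poisson p-value over input of 1e-04 and named a fold of 4 over the surrounding 10 kb, a step that removed 0 peaks in every list. The other header counts of removed peaks do not add up from putative peaks to regions, and the step between them is not given in the sources used here. No region was called on pooled samples. The deposited signal of a region was its tag number per 10000000 tags of the ChIP library, per the file headers. The deposited score was the authors' region score from HOMER, not adjusted for depth. The deposited fold was the ratio of ChIP over input tags at equal depth, with a p-value of the authors' caller per region. In 5 lists the authors' ChIP tags were scaled to the input, and in the H3.1 24 h list the input tags were scaled to the ChIP library. A region missing from a list is therefore a region that was not called, and does not show that the histone was absent there. The score and fold were used to describe, rank or filter regions within a list.

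ChIP depth, from the file headers, was 18656173 tags for H3.1 control, 17570988 for H3.1 4 h, 16837079 for H3.1 24 h, 17903759 for H3.3 control, 17793437 for H3.3 4 h and 19576955 for H3.3 24 h. Input depth was recovered from the scaled tag columns as about 15800000, 16600000, 18100000, 16600000, 17700000 and 16600000 tags in the same order. The recovered depths of the H3.1 4 h, H3.3 control and H3.3 24 h inputs are equal within this precision. The lists do not tell whether these were separate libraries or 1 used more than once. ChIP tags per region were whole numbers, to a tolerance of 0.1, in 100% of regions of every list. Each fold is given with an exact 95% interval from the conditional binomial distribution of ChIP and input tags. Regions were called and ranked on these same tags, and the interval makes no allowance for that selection. Each share is given with an exact Clopper-Pearson 95% interval. Both cover counting error only, since 1 library per condition leaves no estimate of the spread between cultures or immunoprecipitations. For this reason no test between conditions was made.

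Genes came from a RefSeq gene table of the matching assembly, with 19974 protein-coding genes on chromosomes 1 to 22 and X. That table gave gene starts and ends without strand, so transcription start sites were not used here. A region was placed at a gene end if it lay within 2 kb of either end of a protein-coding gene. A gene was counted as holding a region if one overlapped its body or the 2 kb on either side. The exon structure of genes, repeats and the genome sequence were not used here. Regions on unplaced contigs and chromosome Y were left out of placement, overlap and naming.

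Overlap of 2 lists, at 1 bp or more, was compared with 1000 circular shifts of the longer list along each chromosome in a two-sided permutation test. P-values were adjusted by Benjamini-Hochberg over the 15 pairs. Chromosome lengths were taken from the largest coordinate seen, and gaps in the assembly were not removed. These tests compare 2 lists with random placement, not 2 conditions. The share of H3.1 control regions that overlapped an H3.3 region was computed for regions kept in, and absent from, the H3.1 list at the same time, beside 1000 shifts of the H3.3 list.

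The 16 gene lists, 613 entries in all, were fixed before the data were examined, as were the main tests and most alternatives. The gene windows were planned around transcription start sites, and without strand both gene ends were used instead. All but 1 entry had a place in the gene table. For each list the number of members with a region was set against 10000 random lists matched on gene length in 20 bins, with a two-sided permutation p adjusted by Benjamini-Hochberg over the lists of a library. Gene families were also tested with gene order kept, by shifting the calls, less the rate of their gene length bin, by every possible step along the genes in genome order. Named genes followed a rule fixed before the data were examined, except that the nearest gene end replaced the nearest transcription start site. The rule took the 5 genes with the highest-scoring regions per library, and 5 per direction of each treated and control pair with a region in 1 list and none in the other. It also took up to 4 members per gene list and library with the highest scores. Some genes that this rule names are not reported here. A region touching several genes named the one with the nearest end. Coordinates are those of the deposited lists, on hg38.

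The overlap and gene list tests were tested on simulated data. With 10% of 9973 simulated regions planted in a second list, the overlap ratio was 8.44 (permutation p = 0.004975, the smallest that the shifts drawn there allow), and with none planted it was 1.09 (permutation p = 0.333). The simulated regions lay at random positions along chromosomes, without the crowding of the real lists. They therefore do not show how the overlap test behaves under such crowding. Among random lists of 40 genes on the H3.3 control calls, 5% had p under 0.05. Of lists with 20 called members of 40, 100% did. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Chromosome arms were split at the widest stretch without annotated genes. To compare list lengths at equal depth, ChIP tags of H3.1 control and H3.3 24 h were thinned to the shallowest library in 20 random draws, and regions were kept that still had a score of at least 12, that library's tag threshold, and met the fold and p-value required over input. Regions could be lost but not gained. Alternatives covered the fold threshold, the overlap rule, equal list length, local shifts, the gene window and the matching of random lists.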

Results

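H3.1 and H3.3 were mapped in 6 ChIP-seq libraries of MCF10AER/vSrc mammary epithelial cells, 1 per histone in control cells and 4 h and 24 h after D-alanine. H3.1 is the histone variant deposited mainly during DNA replication, and H3.3 the variant deposited through the cell cycle. Each condition had 1 ChIP library and 1 input, so differences between conditions have no replicate check. Depth was similar, with 16837079 to 19576955 ChIP tags per library. The file headers give similar numbers of putative peaks, between 523357 and 653403. The number of enriched regions in the final lists spanned a 22.4-fold range.

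In control cells, H3.1 was called at 44990 regions covering 27.8 Mb, at or near 8851 of 19974 protein-coding genes. After D-alanine the H3.1 list was shorter, with 7949 regions (4.26 Mb, 3420 genes) at 4 h and 13641 regions (7.47 Mb, 5672 genes) at 24 h. The share of H3.1 ChIP tags inside regions was 4.74% in control cells, 0.92% at 4 h and 1.59% at 24 h. H3.3 took another course. It was called at 9867 regions (5.43 Mb, 4245 genes) in control cells, 3628 regions (1.89 Mb, 1791 genes) at 4 h and 81405 regions (52.3 Mb, 12017 genes) at 24 h. The share of H3.3 tags inside regions was 1.3%, 0.37% and 8.9%. The H3.3 list at 24 h was thus 8.25 times the length of its control list, whereas the H3.1 list at 24 h was 0.303 times its own.

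**Figure D1:**
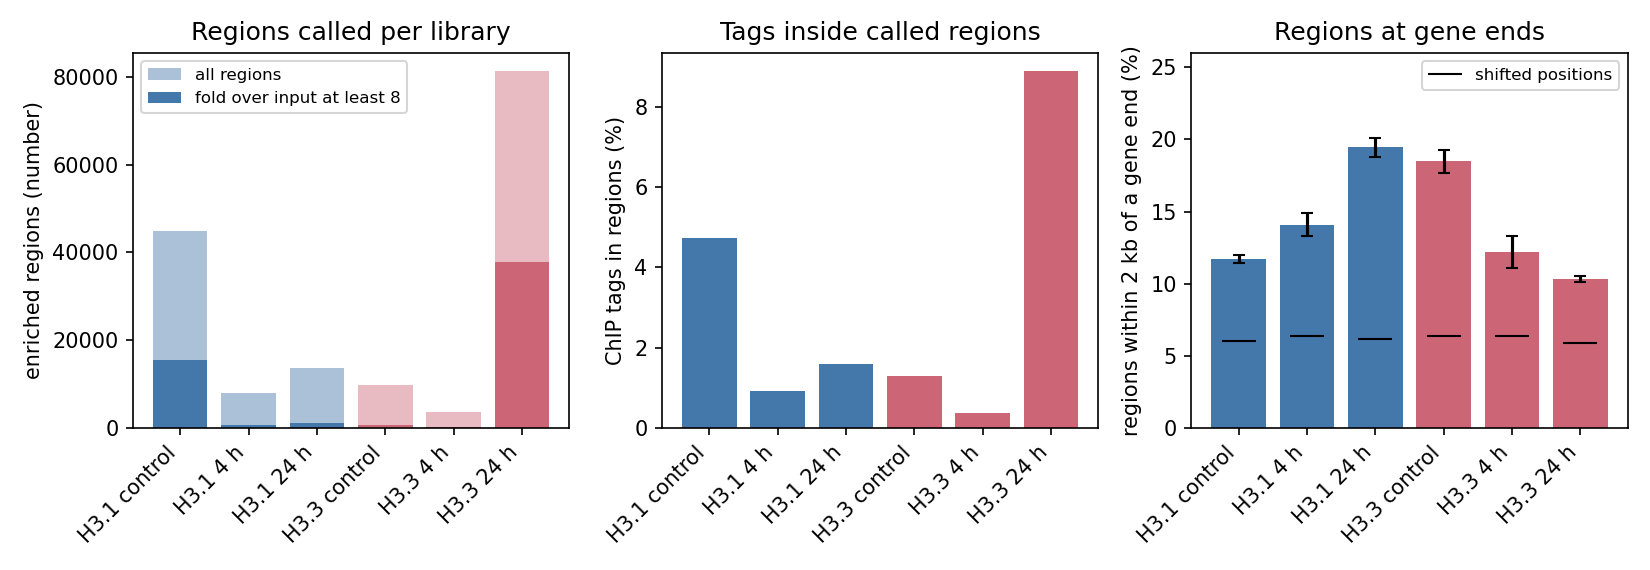
Bars give, for each of the 6 ChIP libraries (H3.1 in blue, H3.3 in red), the number of enriched regions (pale) and of those with a fold over input of at least 8 (dark), the percent of ChIP tags inside regions, and the percent of regions within 2 kb of a gene end with exact 95% intervals and the mean at shifted positions (black dashes). H3.1 control (44990) and H3.3 24 h (81405) had the longest lists, and their shares at gene ends were 11.7% and 10.3%.

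The regions of the long lists had a higher fold over input but not more ChIP tags. Median fold over input was 6.21 in the H3.1 control list and 7.34 in the H3.3 24 h list, against 4.63 to 4.98 in the other 4 lists, close to the required fold of 4. Median normalised tags per region, the tag number per 10000000 tags of the library, were 9.11 and 9.19 in the long lists and 8.99 to 11.2 in the others. Regions without any input tag made up 8.21% and 13.3% of the long lists and 0.557% to 1.02% of the others. Regions with a fold of at least 8 numbered 15499 for H3.1 control, 554 for H3.1 4 h and 1096 for H3.1 24 h. For H3.3 they numbered 682 in control cells, 279 at 4 h and 37853 at 24 h. Median region width was 500 bp in every library, and regions over 1 kb made up 6.61% of the H3.1 control list and 8.71% of the H3.3 24 h list, against 0.276% to 1.53% elsewhere.

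The highest-scoring H3.1 regions in control cells included those at CAMK2B, a calcium/calmodulin-dependent kinase subunit, AQP1, a water channel, ELFN1, a synaptic transmembrane protein, and ADAMTS2, a procollagen-processing protease. The CAMK2B region (chromosome 7, 44216354 to 44216984, within 2 kb of a gene end) held 28.9 normalised tags at a fold over input of 5.08 (exact 95% interval 2.49 to 11.7). The AQP1 region (chromosome 7, 30913497 to 30913997, within 2 kb of a gene end) held 24.7 normalised tags at a fold of 4.87 (2.28 to 12). At 4 h the leading H3.1 regions lay at AEBP1, TLX3, GARIN5B, MAD1L1 and TMEM184A. AEBP1 encodes a secreted collagen-binding protein, TLX3 a homeobox factor, and MAD1L1 a spindle checkpoint protein. The AEBP1 region (chromosome 7, 44107768 to 44108268, inside the gene) held 41.5 normalised tags at a fold of 5.31 (2.92 to 10.5). At 24 h they lay at RADIL, CD247, PLEKHA6, TSNARE1 and MICALL2, where CD247 encodes the zeta chain of the T cell receptor complex. The RADIL region (chromosome 7, 4833882 to 4834382, inside the gene) held 36.2 normalised tags at a fold of 6.56 (3.34 to 14.4).

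Few H3.1 control regions overlapped a treated H3.1 region. Of 44966 control regions on chromosomes 1 to 22 and X, 679 overlapped one at 4 h and 919 at 24 h, leaving 98.5% and 98% in the control list alone. The treated lists were much shorter, with 7922 and 13611 regions there, so most control regions could not meet one. In the other direction 91.4% of 4 h regions and 93.3% of 24 h regions were in the treated list alone. By gene, 6269 protein-coding genes held an H3.1 region in control cells and none at 4 h, and 838 held one at 4 h and none in control cells. At 24 h these numbers were 4994 and 1815, with 3857 genes in both lists. If the control and treated lists were independent, 2513 genes would be in both at 24 h. At 4 h, 2582 genes were in both, against 1515. These independent numbers take no account of gene length. Genes with a region in control cells and none at 24 h included AQP1, GPR37L1, a G protein-coupled receptor, and WNT3A, a Wnt ligand. The WNT3A region (chromosome 1, 228009970 to 228010470, inside the gene) had a fold of 10.4 (3.31 to 53). The reverse group was led by MICALL2, GLI4, SFXN2, FAM131A and EEF1D, a translation elongation factor subunit. At 4 h the group without a control region was led by TMEM184A, CRIP2, INS, the insulin gene, LRCOL1 and MNX1, a homeobox factor, and the group without a 4 h region by CAMK2B, AQP1, SUSD4, GPR37L1 and KCNK9, a potassium channel. With each list held to its 3614 highest-scoring regions, 3580 were in the H3.1 control list alone and 3580 in the 24 h list alone, counts that equal length makes alike by construction.

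For H3.3, the leading control regions lay at C9orf43, CLEC20A, HOXA13, CNFN and LY6E. HOXA13 is a posterior HOX factor and CNFN a cornified envelope protein of stratified epithelia. The HOXA13 region (chromosome 7, 27198851 to 27199351, within 2 kb of a gene end) held 41.9 normalised tags at a fold of 4.08 (2.39 to 7.38). The C9orf43 region (chromosome 9, 113410090 to 113410590) lay within 2 kb of an end of that gene and overlapped its neighbour POLE3, which encodes a DNA polymerase epsilon subunit. At 4 h the leading regions lay at LDB3, PACS2, LYPD2, MAML1, a Notch coactivator, and TOP1MT, the mitochondrial topoisomerase. At 24 h they lay at IKBKE, NAV1, EEPD1, TNRC18 and GRB10. All of these lie on the long arm of chromosome 1 or the short arm of chromosome 7. Those arms had the most input tags per region in this list (3.4 and 3.47 on average). Whether this raised the scores, which are not adjusted for depth, was not tested. IKBKE encodes an innate immune kinase and GRB10 an adaptor of insulin and growth factor receptors. The IKBKE region (chromosome 1, 206489928 to 206490560, inside the gene) held 39.3 normalised tags at a fold of 4.07 (2.36 to 7.48). The EEPD1 region (chromosome 7, 36287653 to 36288614, inside the gene) held 32.7 normalised tags at a fold of 10.8 (4.41 to 34.5).

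The H3.3 control list, with 9839 regions, could meet only a small part of the H3.3 24 h list. At 24 h, 80977 of 81370 H3.3 regions (99.5%) had no counterpart in the H3.3 control list, and 8670 protein-coding genes held an H3.3 region at 24 h and none in control cells. These genes were led by IKBKE, NAV1, GRB10, HNRNPA2B1 and STUM, all on those arms of chromosomes 1 and 7. The HNRNPA2B1 region (chromosome 7, 26200793 to 26201293) lay within 2 kb of an end of this splicing factor gene and also of CBX3, a heterochromatin protein, and had a fold of 5.4 (2.54 to 13.2). The longer list did not contain the shorter one. Of 9839 H3.3 control regions, 9446 (96%) had no counterpart at 24 h, and 898 genes held a region in control cells and none at 24 h. That group was led by C9orf43, PANX2, a pannexin, LYNX1, OPLAH, a 5-oxoprolinase of glutathione turnover, and SART1, a splicing factor. By gene the lists shared more, since 3347 genes held a region both in control cells and at 24 h. Independent lists would give 2554, without account of gene length. The OPLAH region (chromosome 8, 144058936 to 144059691, inside the gene) had a fold of 4.07 (2.3 to 7.68). At 4 h, 834 genes held an H3.3 region and none in control cells, led by LYPD2, MAML1, COPE, TMEM132B and ZZEF1, and 3288 held one in control cells and none at 4 h, led by the same 5 genes as the control list itself.

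The placement of regions relative to genes differed between lists. Within 2 kb of a gene end lay 11.7% of H3.1 control regions (95% interval 11.4 to 12), 14.1% at 4 h (13.3 to 14.9) and 19.5% at 24 h (18.8 to 20.1). For H3.3 the share was 18.5% in control cells (17.7 to 19.3), 12.2% at 4 h (11.1 to 13.3) and 10.3% at 24 h (10.1 to 10.5). Shifted positions gave 5.85% to 6.39%, so regions lay at gene ends 1.76 to 3.14 times as often as random placement. With a window of 500 bp the H3.1 shares were 4.51%, 6.16% and 9.5%, and the H3.3 shares 8.09%, 4.59% and 3.89%. Among regions at or above the pooled median fold of 6.21, H3.1 4 h (10.8%) was no longer above H3.1 control (10.9%), and H3.3 24 h (9.46%) no longer below H3.3 4 h (8.92%). Between 54.2% and 61.4% of regions overlapped a protein-coding gene body, against 43.4% to 43.7% at shifted positions.

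Comparing the positions of the 2 histones, the H3.1 control list and the H3.3 24 h list shared the most regions. Of 44966 H3.1 control regions, 15199 (33.8%, 33.4 to 34.2) overlapped an H3.3 region at 24 h, 8.4 times the number at shifted positions (adjusted permutation p = 0.00115, from the smallest p that 1000 shifts can give). The other 4 lists shared regions with one another at 9.84 to 13 times the shifted number, although this was only 4.15% to 8.33% of the shorter list. The highest of these ratios was between H3.3 control and H3.1 24 h, with 820 of 9839 regions shared. Regions of these 4 lists fell in the H3.1 control list at 3.22 to 4.09 times the shifted number, but at 1.45 to 1.91 times with shifts within 1 Mb and 1.04 to 1.33 times with shifts of 2 to 20 kb, where 2 of the 4 did not pass. Among the 4 lists themselves these ratios were 3.69 to 4.42 and 2.38 to 2.88. Their ratios to the H3.3 24 h list were 1.42 for H3.1 4 h, 1.13 for H3.1 24 h, 1.08 for H3.3 control and 1.65 for H3.3 4 h. The adjusted permutation p for H3.1 24 h was 0.138 and for H3.3 control 0.397. Without chromosome 19 the H3.1 24 h ratio was 1.2 and passed (adjusted permutation p = 0.0225). With shifts within 1 Mb the last set of ratios was 0.853, 0.674, 0.65 and 1.01, so 3 of the 4 lists then met H3.3 24 h regions less often than nearby positions did. The H3.1 control and H3.3 24 h lists kept a ratio of 4.06 under those shifts.

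**Figure D2:**
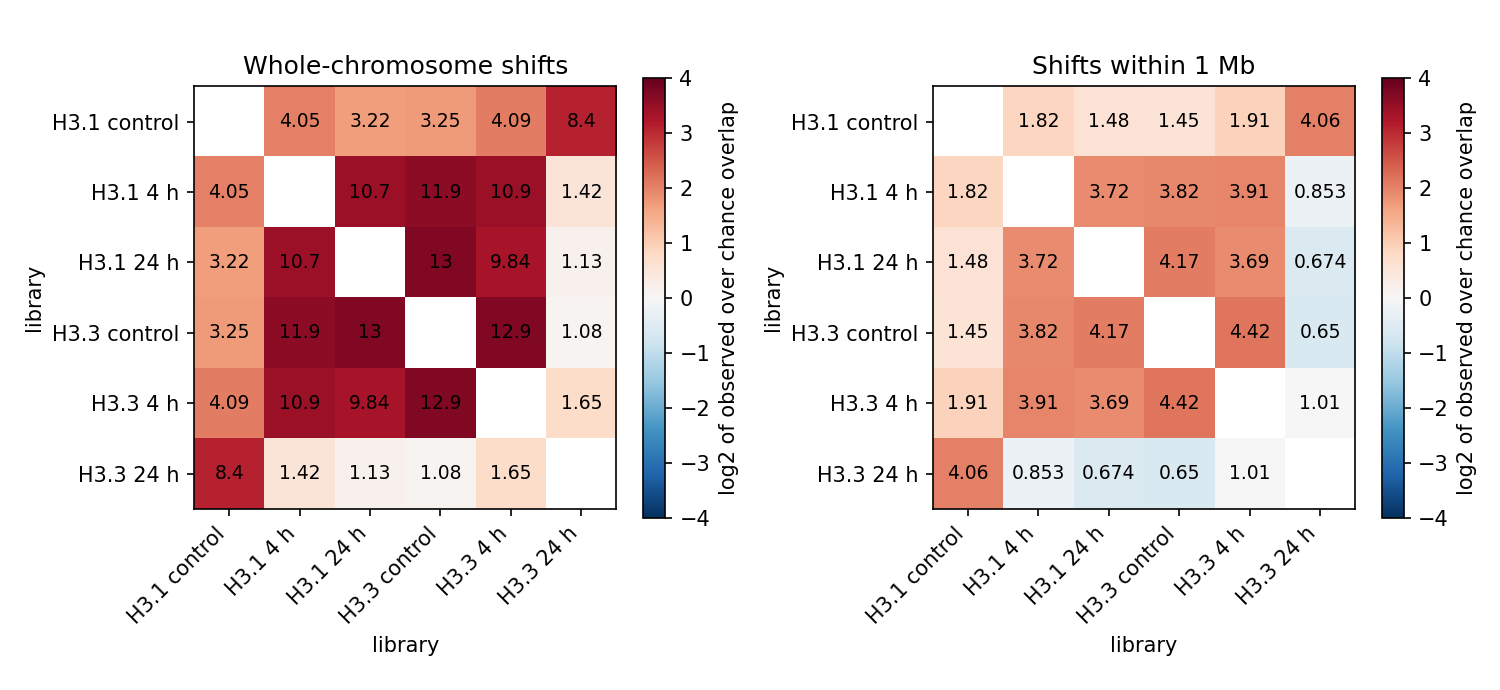
Each cell gives the number of shared regions between 2 of the 6 libraries divided by the mean number over 1000 shifts, along whole chromosomes (left) and within 1 Mb (right), with colour on a log2 scale. The ratio of H3.1 control with H3.3 24 h was 8.4 and 4.06, and that of H3.3 control with H3.3 24 h was 1.08 and 0.65.

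The design pairs both histones at the same times, which asks whether H3.3 was found where H3.1 regions were no longer called. Of the 44047 H3.1 control regions absent from the H3.1 24 h list, 15026 (34.1%, 33.7 to 34.6) overlapped an H3.3 region at 24 h. Of the 919 that were kept, 173 did (18.8%, 16.3 to 21.5). The difference was 15.3 percentage points, against -0.129 at shifted positions (permutation p = 0.000999, the smallest possible). In control cells H3.3 regions met 1.46% of the regions later absent and 3.81% of those kept. At 4 h the order was as in control cells, the reverse of that at 24 h. H3.3 regions met 0.673% of the 44287 absent regions (0.599 to 0.753) and 1.91% of the 679 kept regions (1.02 to 3.25), which rests on 13 shared regions. Among the 3614 highest-scoring regions of each list, the 24 h difference was 5.02 percentage points (permutation p = 0.002). Only 1 of 34 kept regions was covered (2.94%, 0.0744 to 15.3), an interval that contains that of the absent regions (7.96%, 7.09 to 8.9). The shifted lists covered 0.215% of kept and 0.341% of absent regions. That p therefore does not show that absent and kept regions differed at the observed coverage. The 4 h difference turned to 0.818 (permutation p = 0.124). A split by the H3.3 control list gave a similar contrast at 24 h. H3.1 control regions that met an H3.3 control region overlapped H3.3 24 h regions in 18.4% of cases (15.5 to 21.5), against 34% of the others. The H3.3 control and H3.1 24 h lists share regions. Among only the regions absent from the H3.1 24 h list, these shares were 18.6% (15.7 to 21.8) and 34.3%.

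Among the 16 fixed gene lists, 3 departed from length-matched random lists, each in the H3.1 24 h library. In that library, 25 of 44 Src, MAPK and growth factor signalling genes held an H3.1 region, against 13.8 in random lists (adjusted permutation p = 0.0048). Its leading members included JUN and EGR1, immediate-early transcription factors, and DUSP4, a MAP kinase phosphatase. The JUN region (chromosome 1, 58783045 to 58783672, within 2 kb of a gene end) held 29.7 normalised tags at a fold of 4.14 (2.22 to 8.31). Of 45 homeobox and developmental regulators, 22 held an H3.1 region at 24 h, against 10.6 (adjusted permutation p = 0.0048). They were led by PAX2, NKX2-5, GATA2 and DLX5. Of 42 housekeeping and ribosomal protein genes only RPL13 held one, against 8.7 (adjusted permutation p = 0.0064). None of the 3 passed when regions were required at gene ends (adjusted permutation p = 0.0528 for signalling, 0.354 for homeobox and 0.0528 for housekeeping genes), or at equal list length (0.355, 0.927 and 0.355). Whether these lists differed between libraries was not tested. In control cells 22 of 44 signalling genes, 25 of 45 homeobox genes and 9 of 42 housekeeping genes held an H3.1 region, and at 4 h 8, 10 and 0 did. At equal list length the homeobox list passed for H3.3 control, with 12 members against 4.34 (adjusted permutation p = 0.0288).

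The mesenchymal and epithelial lists did not pass in any library against length-matched lists at full list length. Mesenchymal genes of the epithelial-mesenchymal transition held an H3.1 region in 22 of 40 cases in control cells, 3 at 4 h and 9 at 24 h, and an H3.3 region in 8, 1 and 30 cases. In the H3.3 24 h list they were led by LOX, TGFB2, PDGFRB and INHBA. The LOX region (chromosome 5, 122078226 to 122078852, within 2 kb of a gene end) held 21.5 normalised tags at a fold of 7.11 (2.82 to 23). Random lists gave 25.3 members there (adjusted permutation p = 0.554), but at equal list length 9 members against 3.13 passed (adjusted permutation p = 0.0432). Equal list length ranks regions by a score not adjusted for depth, and random lists were not matched on chromosome arm. The LOX region lay on the long arm of chromosome 5, where regions of this list held 2.85 input tags on average. Whether such arms raised the count was not tested. Epithelial identity genes held an H3.3 region in 5 of 36 cases in control cells, 3 at 4 h and 30 at 24 h, the last against 22 in random lists (adjusted permutation p = 0.0672). Against random lists not matched on length, which gave 21.7, it passed (adjusted permutation p = 0.032). ELF3, LAMB3, GRHL2 and KRT17 led them, and the GRHL2 region (chromosome 8, 101648200 to 101648833, inside the gene) was 1 of 12 at that epithelial transcription factor gene. For H3.1 the epithelial counts were 19, 4 and 11.

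Lists of oxidative stress, DNA damage and drug resistance genes did not depart from random lists in any library. Of 40 NRF2 and antioxidant genes, 14, 4 and 10 held an H3.1 region in control cells, at 4 h and at 24 h, and 8, 1 and 22 an H3.3 region. At 24 h the leading H3.1 members included TXN, GPX4 and SOD2, which encode thioredoxin, a peroxidase that reduces lipid peroxides, and mitochondrial superoxide dismutase. The leading H3.3 members were ABCC1, GPX3, SQSTM1 and TKT. Of 40 DNA damage and p53 target genes, 15, 8 and 5 held an H3.1 region and 5, 2 and 22 an H3.3 region. PARP1, a DNA break sensor, led the H3.3 24 h list with 16 regions, the top one at chromosome 1, 226404455 to 226405396, inside the gene. Of 39 drug efflux and drug metabolism genes, 17, 6 and 14 held an H3.1 region and 8, 5 and 24 an H3.3 region. ABCA13 held 47 H3.3 regions at 24 h.

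Stemness genes held an H3.1 region in 14, 11 and 14 of 38 cases and an H3.3 region in 10, 9 and 19 cases. The 9 at 4 h, led by TERT, GLI2, DLK1 and POU5F1, compared with 3.33 in random lists (adjusted permutation p = 0.106). Of 35 genes for H3 variants, their chaperones and remodellers, 12, 4 and 4 held an H3.1 region and 7, 4 and 16 an H3.3 region. CABIN1, a subunit of the HIRA complex that deposits H3.3, held 28 H3.3 regions at 24 h, and HIRA itself held 13. Of 39 polycomb and heterochromatin genes, 19, 11 and 14 held an H3.1 region and 11, 3 and 28 an H3.3 region. Of 40 cell cycle and replication genes, 12, 4 and 12 held an H3.1 region and 2, 0 and 20 an H3.3 region. For H3.3 the signalling counts were 12, 5 and 31, the homeobox counts 16, 4 and 30 and the housekeeping counts 3, 1 and 17.

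Markers of lineages not in culture held regions as well, and none of these lists departed from length-matched lists in the main comparison. Neuronal adhesion and synapse genes, which are long, held an H3.1 region in 31, 20 and 29 of 40 cases and an H3.3 region in 22, 7 and 35 cases. In the H3.3 24 h list they fell below random lists with gene ends only, 2 against 10.5 (adjusted permutation p = 0.0192), and at equal list length, 0 against 5.94 (0.0432). Immune markers held one in 18, 5 and 7 of 35 cases for H3.1 and 9, 3 and 22 for H3.3. Fibroblast and endothelial markers gave 16, 5 and 10 of 25 for H3.1 and 5, 2 and 20 for H3.3. Hepatic and muscle markers gave 23, 9 and 10 of 34 for H3.1 and 10, 6 and 25 for H3.3.

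**Figure D3:**
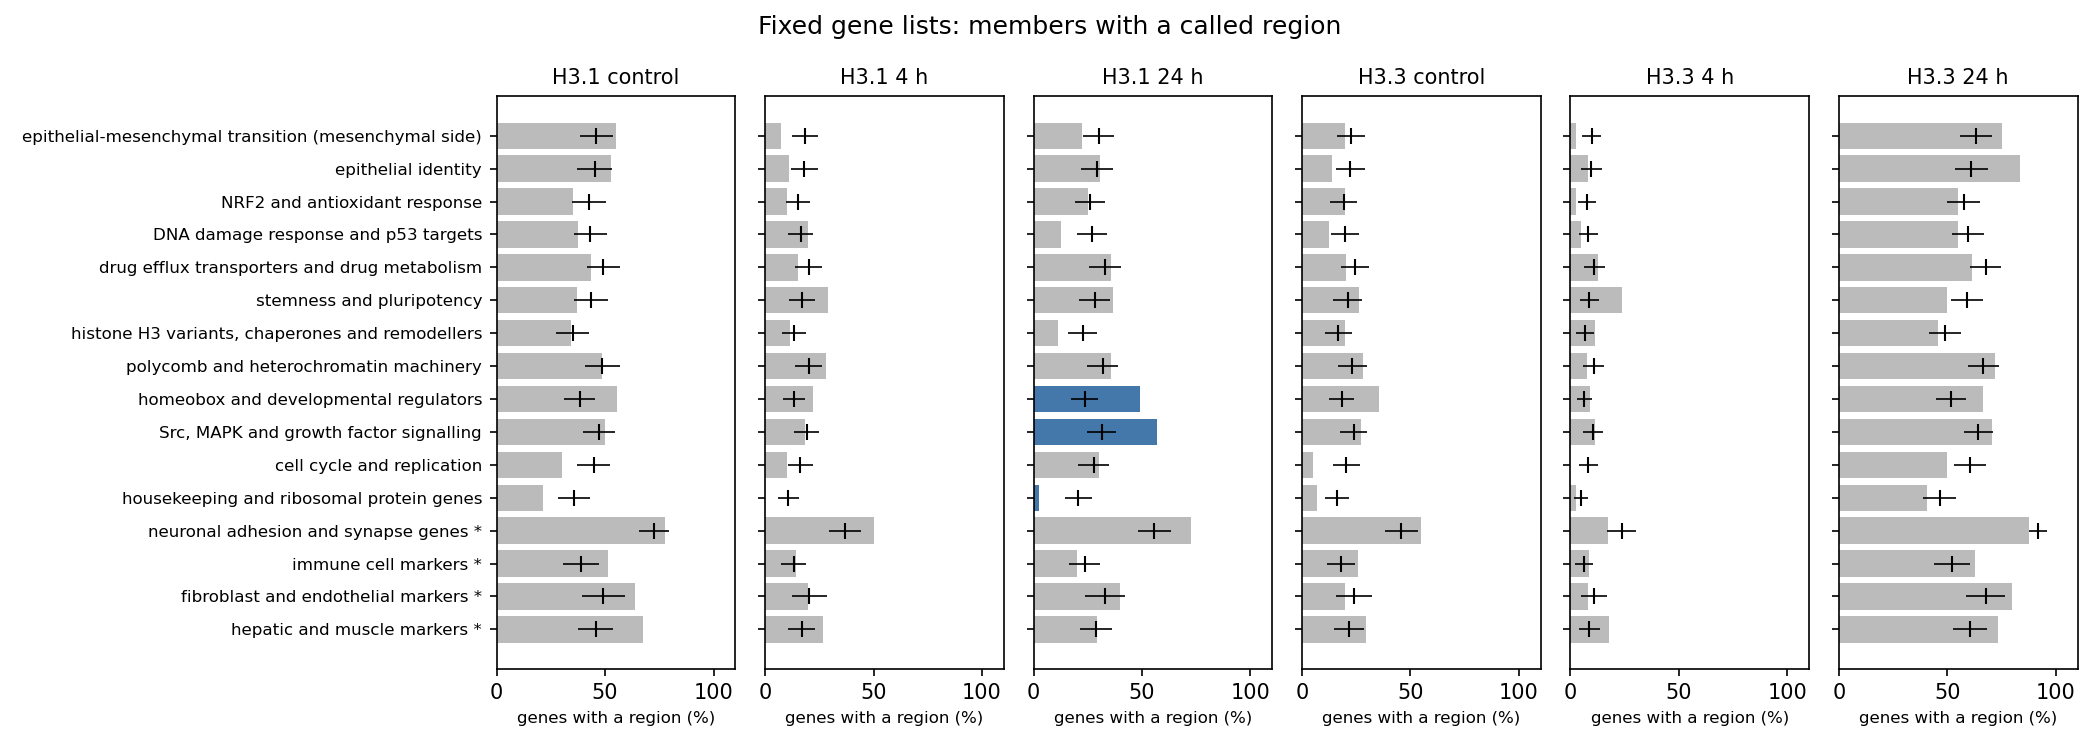
Bars give the percent of members of each fixed gene list with a called region in the gene or within 2 kb, per library; black marks give the mean and SD of 10000 length-matched random lists, and lists with an asterisk are markers of lineages not in culture. Coloured bars, all in H3.1 24 h, passed an adjusted p of 0.05, and grey bars did not.

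Along chromosomes, the 2 long lists were dense on arms where the others were not. Region density on the long arm of chromosome 1 was 1.84 times the library mean for H3.1 control and 2.24 times for H3.3 24 h. In the other 4 lists it was 0.53 for H3.1 4 h, 0.752 for H3.1 24 h, 0.602 for H3.3 control and 0.869 for H3.3 4 h. The short arm of chromosome 7 gave 2.23 and 2.53 in the long lists and 0.736 to 0.998 in the others. Many of the leading regions named above lay on these arms, in the long lists and also in H3.1 4 h, H3.1 24 h and H3.3 control (AEBP1, RADIL and HOXA13, for example). Whether the score, which is not adjusted for depth, favoured these arms was not tested. The short arm of chromosome 19, a gene-rich arm, gave 2.39 and 1.71 in the long lists and 4.37 to 5.42 in the others. Within 5 Mb of a chromosome end lay 21.4% of H3.1 control regions (21.1 to 21.8) and 13.2% of H3.3 24 h regions (13 to 13.4), against 29.4% to 33.8% in the other lists. Without chromosomes 1 and 7, the order of the 6 lists by length was the same.

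**Figure D4:**
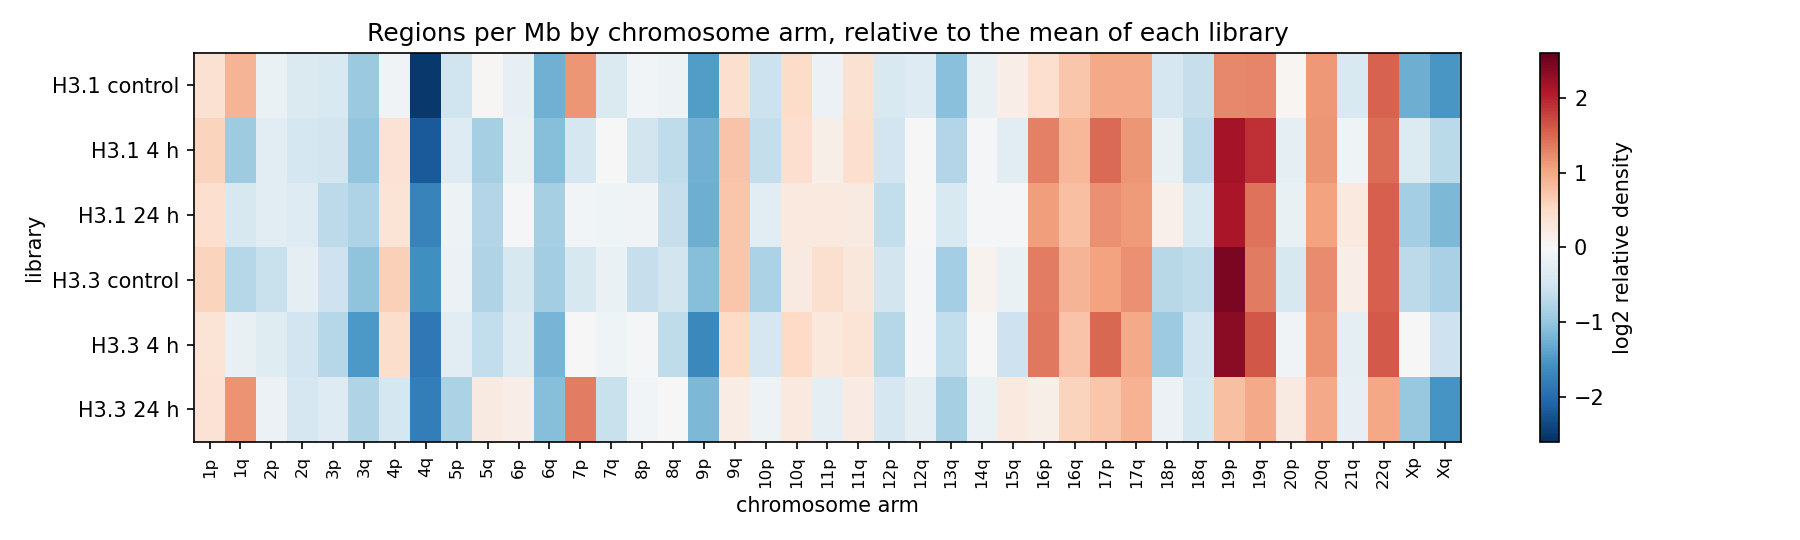
Colour gives, on a log2 scale, the number of regions per Mb on each chromosome arm (horizontal axis) relative to the mean of each library (vertical axis). The long arm of chromosome 1 and the short arm of chromosome 7 were above the mean in H3.1 control (1.84 and 2.23) and H3.3 24 h (2.24 and 2.53) and below it in the other 4 libraries.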

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

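The split among regions absent from the H3.1 24 h list and the tests of input depth, of a weaker immunoprecipitation and of a mislabelled library were chosen after the result was seen. From control to 24 h, H3.1 and H3.3 moved in opposite directions in 5 measures, and at 4 h in 3 of them. None of these differences was tested, since each condition had 1 library. The number of regions at 24 h was 0.303 times control for H3.1 and 8.25 times for H3.3, and the percent of ChIP tags in regions 0.335 and 6.85 times. The share of regions at gene ends was 1.67 times control for H3.1 and 0.557 times for H3.3 at 24 h, and 1.21 and 0.659 times at 4 h. The higher 4 h share for H3.1 was not kept at the pooled median fold, where the share was 10.8% against 10.9% in control cells. The share within 5 Mb of a chromosome end was 1.44 and 0.391 times at 24 h, and 1.46 and 0.87 times at 4 h. The density ratio of the long to the short arm of chromosome 1 was 0.398 and 4.34 times at 24 h, and 0.254 and 1.69 times at 4 h.

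The opposite change in region number was weighed first. Sequencing depth of the ChIP libraries is argued against, because after thinning to the shallowest library the smaller ratio of list lengths, H3.1 control over H3.1 24 h, was still 2.75. Input depth is argued against for H3.3, whose 24 h over control input depth ratio was 1.00, although whether these were 2 inputs or 1 is not known. For H3.1 it was not tested. A weaker immunoprecipitation of the same H3.3 landscape in control cells predicts H3.3 control regions inside 24 h regions. H3.3 control regions met 24 h regions at 0.65 times the rate of positions within 1 Mb. That argues against it only if the control calls were mostly H3.3 sites. If most were background calls, the positions cannot decide, and the control median fold of 4.63 was close to the limit of 4. The whole-chromosome ratio was 1.08 (adjusted permutation p = 0.397), and no setting gave a ratio above 1 past the threshold, with 1.17 at equal list length (0.77), 1.17 at the pooled median fold (0.424) and 1.14 without chromosome 19 (0.161). A failed immunoprecipitation in any of the 4 libraries with short lists, the 2 treated H3.1 libraries included, whose median folds were 4.63 to 4.98, and a redistribution of both histones after D-alanine, stay open and were not tested.

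The sharing between H3.1 control and H3.3 24 h was weighed second. Crowding of both lists into the same parts of the genome is argued against as the whole cause, because the overlap was 2.68 times that at positions shifted by 2 to 20 kb. Replacement of H3.1 by H3.3 predicts more H3.3 where H3.1 was no longer called, and that difference was 15.3 percentage points at 24 h. A split by presence in the H3.3 control list gave 15.7 points, also among regions absent from the H3.1 24 h list, so the contrast cannot be told apart from a general distance between the shorter lists and the H3.3 24 h list. A mislabelled library also stays open, since 1 library per condition offers no second one to compare.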

How the results depend on the processing

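The alternatives with a fold of at least 8, without chromosomes 1 and 7, with shifts of 2 to 20 kb and with only regions absent from the H3.3 control list, and all those on gene families, were chosen after seeing the data. No paired test between conditions was made, with 1 library per histone and time. Alternatives on repeats, on an annotation column and on gene names in the lists were not run, since the lists hold neither and repeat positions were not used here. The order of the 6 lists by length was the same on chromosomes 1 to 22 and X and after merging regions within 1 kb. Depth limits the folds, since the median region held 2 to 4 input tags.

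Raising the fold threshold removed regions by construction. At or above the pooled median fold of 6.21, H3.1 had 22600, 1363 and 2580 regions and H3.3 1556, 809 and 51967 (control, 4 h, 24 h). At a fold of at least 8 the numbers were 15499, 554 and 1096, and 682, 279 and 37853. The share at gene ends with a 500 bp window, smaller by construction, was 4.51%, 6.16% and 9.5% for H3.1 and 8.09%, 4.59% and 3.89% for H3.3. At the pooled median fold it was 10.9%, 10.8% and 14.8%, and 15.6%, 8.92% and 9.46%, so that H3.1 4 h was no longer above H3.1 control and H3.3 24 h no longer below H3.3 4 h. The cause was not tested.

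Overlap ratios of the 6 pairs among the 4 shorter lists and of H3.1 control with H3.3 24 h stayed above 1 and past the threshold under every setting run. Ratios to the H3.3 24 h list did not. For H3.1 4 h they were 1.05 with half-length overlap, 0.976 at equal list length, 0.853 within 1 Mb, 1.04 at the pooled median fold and 0.672 with shifts of 2 to 20 kb. For H3.1 24 h they were 0.538 with half-length overlap, 0.674 within 1 Mb, 0.756 at the pooled median fold, 0.542 with shifts of 2 to 20 kb and 1.2 without chromosome 19, where the ratio passed (adjusted permutation p = 0.0225, against 0.138). For H3.3 control they were 0.48 with half-length overlap, 0.65 within 1 Mb and 0.538 with shifts of 2 to 20 kb. For H3.3 4 h they were 1.31 at equal list length, 1.01 within 1 Mb, 1.22 at the pooled median fold and 0.826 with shifts of 2 to 20 kb. With those shifts H3.1 24 h and H3.3 control met H3.1 control regions at ratios of 1.07 (adjusted permutation p = 0.0621) and 1.04 (0.333). The cause was not tested.

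H3.3 coverage of H3.1 control regions was 0.411% at 4 h and 28.9% at 24 h with half-length overlap, and 0.802% and 7.91% at equal list length, where the 4 h difference of absent minus kept regions turned to 0.818 percentage points and the 24 h difference was 5.02, against 15.3. Only among regions absent from the H3.3 control list, the 24 h difference was 15.3. Equal list length caps the regions in 1 list alone, by construction, at 3546 and 3546 for H3.1 4 h (control only, treated only), 3580 and 3580 for H3.1 24 h, 3519 for H3.3 4 h (control only) and 3607 and 3607 for H3.3 24 h. Counting neighbours within 5 kb as shared left 4191 H3.1 4 h, 7629 H3.1 24 h and 5357 H3.3 control (against 24 h) regions unshared. Gene lists past the threshold numbered 0 in H3.1 24 h with gene ends only and at equal list length. They numbered 1 in H3.3 24 h with gene ends only (neuronal, fewer), and at equal list length 1 in H3.3 control (homeobox) and 2 in H3.3 24 h (mesenchymal, more; neuronal, fewer). With random lists not matched on length they numbered 2 in H3.1 control, 2 in H3.1 4 h, 4 in H3.1 24 h, 1 in H3.3 control and 2 in H3.3 24 h, where long neuronal genes entered each time. Of the gene families, solute carriers in H3.3 24 h and developmental transcription factors in H3.1 control turned direction at equal list length (adjusted permutation p = 1 for both).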

Other observations

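The gene families in this part, and the tests on arms of chromosomes 1 and 7, were chosen after the data were seen. The prediction for the test with shifts of 2 to 20 kb was written before its result was seen. Of 11 families tested, each passed in at least 1 library against length-matched random lists, and 5 are described. Clustered protocadherins, cell adhesion genes in tandem arrays, held an H3.1 region in 38 of 53 cases in control cells, 31 at 4 h and 38 at 24 h, against 26.2, 10.8 and 18.4 in length-matched random lists (adjusted permutation p = 0.0044, 0.0011 and 0.000733). For H3.3 the counts were 33, 10 and 41, against 13.7, 5.88 and 36.1 (adjusted permutation p = 0.0011, 0.334 and 0.222). With gene order kept, the H3.1 4 h call remained (adjusted permutation p = 0.0496). Those of H3.1 control, H3.1 24 h and H3.3 control did not (0.397, 0.105 and 0.122). The H3.1 4 h call in turn did not pass with gene ends only, 5 against 3.08 (adjusted permutation p = 0.471). Nor did it pass at equal list length, 10 against 5.43 (adjusted permutation p = 0.13). Developmental transcription factors of 7 families, among them PAX, FOX, SOX, TBX, LHX and NKX, held an H3.1 region in 60, 31 and 54 of 121 cases, against 45.8, 16.1 and 28.2 (adjusted permutation p = 0.0147, 0.0022 and 0.000733), and an H3.3 region in 40 cases in control cells, against 22 (adjusted permutation p = 0.00147). Their H3.3 counts at 4 h and 24 h were 10 and 67 (adjusted permutation p = 0.616 and 0.421). For olfactory receptors, also in tandem arrays, counts were low. Of 392, 29, 5 and 10 held an H3.1 region, against 105, 32.9 and 61.8, and 5, 5 and 36 an H3.3 region, against 45.9, 14.6 and 138. The adjusted permutation p was 0.0638 for H3.3 4 h and 0.0011 or below in the other 5 libraries. Of 39 beta-defensins, antimicrobial peptide genes in clusters, 3, 0 and 0 held an H3.1 region, against 12.3, 3.52 and 6.93 (adjusted permutation p = 0.00293, 0.112 and 0.00275), and 0, 0 and 3 an H3.3 region, against 5.54, 1.49 and 16 (adjusted permutation p = 0.00733, 0.595 and 0.000733). Only the H3.3 24 h call remained with gene order kept. The adjusted permutation p was then 0.0875 in H3.1 control, 0.105 in H3.1 24 h and 0.129 in H3.3 control. Of 40 HOX cluster genes, 16, 3 and 15 held an H3.1 region, against 12.8, 4.03 and 7.53 (adjusted permutation p = 0.35, 0.897 and 0.0163), and 4, 1 and 25 an H3.3 region, against 6.01, 1.62 and 17.1 (adjusted permutation p = 0.514, 1 and 0.0308). Neither 24 h call remained with gene order kept (adjusted permutation p = 0.136 for H3.1 and 0.127 for H3.3).

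The length-matched random lists draw scattered genes, whereas members of a cluster are neighbours and not independent. With gene order kept, so that clusters stay clusters, transcription factors passed in all 4 libraries where they had passed, and olfactory receptors in 4 of 5. Protocadherins then passed in 1 of 4 (H3.1 4 h, adjusted permutation p = 0.0496), beta-defensins in 1 of 4 (H3.3 24 h, 0.00624) and HOX genes in 0 of 2. With gene ends only these numbers were 3 of 4, 5 of 5, 2 of 4, 4 of 4 and 0 of 2 in the same order, and at equal list length 3 of 4, 4 of 5, 3 of 4, 0 of 4 and 0 of 2. Among families not described, potassium channels kept 4 of 4 calls with gene order kept and collagens 3 of 3. Solute carriers kept 2 of 3, C2H2 zinc finger genes 2 of 4, keratin-associated proteins 0 of 1 and replication-dependent histones 0 of 2. At equal list length collagens kept 3 of 3 and potassium channels 0 of 4.

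Some long genes held many regions. PRDM16, a zinc finger transcription factor gene of 369 kb, held 65, 40 and 26 H3.1 regions and 40, 18 and 20 H3.3 regions (control, 4 h, 24 h). PTPRN2, a phosphatase-like gene of 1049 kb, held 106, 28 and 40, and 24, 11 and 61. SDK1, a cell adhesion gene of 968 kb, held 72, 1 and 7, and 2, 1 and 134.

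Regions of the 4 shorter lists lay close to the fold limit, which raises the question of chance calls. Independent chance fluctuations of single libraries are argued against as the whole cause, since the 6 pairs of these lists shared regions at a median of 2.52 times the rate at positions shifted by 2 to 20 kb. Between 4.15% and 8.33% of the shorter list was shared, so chance may still account for part of the remainder. A bias common to these libraries, such as base composition, needs the genome sequence and was not tested. Nor is it known whether H3.1 4 h and H3.3 control, whose recovered input depths are equal, shared an input.

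The density of the long lists on the long arm of chromosome 1 may reflect extra copies of that arm in the cell line. In that case input tags per region would be higher there than on the short arm. The ratio was 1.3 (1.26 to 1.34) in H3.1 control and 1.5 (1.47 to 1.54) in H3.3 24 h, but 0.753 (0.661 to 0.857) in H3.3 4 h, 0.851 (0.772 to 0.937) in H3.1 4 h, 0.927 (0.859 to 1) in H3.3 control and 0.991 (0.933 to 1.05) in H3.1 24 h. For the short over the long arm of chromosome 7 it was 1.51 (1.44 to 1.57) in H3.1 control and 1.61 (1.55 to 1.67) in H3.3 24 h, and 1.28, 1.24, 1.17 and 0.852 in H3.1 4 h, H3.1 24 h, H3.3 control and H3.3 4 h. Input tags are known only inside called regions, which were chosen partly by their input, so copy number and enrichment cannot be told apart for the long arm of chromosome 1. All 6 libraries are of the same cell line. Extra copies that acted alike on every list would therefore not account for the difference from the other 4 lists. There the density on that arm was 0.53 to 0.869 times the library mean. Whether extra copies act differently on lists close to the fold limit was not tested.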
